A study of Mus musculus with 6 samples.

How the data were processed

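Gene expression was measured by RNA sequencing in 6 libraries from sorted mouse bone marrow cells: 2 from recipients of marrow transduced with GFP alone at 4 weeks (mock), 2 from recipients of marrow transduced with Evi1 and GFP at 4 weeks (preleukemia) and 2 at 6 months (leukemia). Per the labels' protocols, cells positive for GFP and c-kit and negative for lineage markers were sorted by flow cytometry, total RNA was extracted with Nucleospin RNA, and libraries were made with the NEBNext Ultra RNA kit. The kit by its name does not mark the strand, so antisense transcripts are not separable. The submitters' processing notes name CASAVA 1.8.2 and the build GRCm38 without their roles. The aligner, the counting tool and the annotation release are not given in the sources used here, nor is it stated that the libraries of a group came from separate mice.

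The deposited table gave 1 value per gene and library in RPKM for 38924 rows. The unit was inferred from the values: multiplied by the exon length of the gene in GENCODE M21, values under 20 reads fell within 0.02 of a whole number of reads in 64.0% to 65.8% of cases (4% by chance), and 53.8% to 54.6% over all values. The step gave each library's total, 16922992 to 21641740 reads, and 3 reads on a gene of 1 kb were worth 0.139 to 0.177 RPKM, a floor for counting error alone. Of the rows, 35428 (91.0%) matched 1 gene of GENCODE M21, and gene locations are those of that release on GRCm38. 19136 rows were 0 in every library, 27 carried names that a spreadsheet had turned into dates, and 2 names stood on 2 rows each.

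Groups were compared with limma 3.58.1 in R 4.3.3. RPKM values were used on the scale of log2(RPKM + 1), and genes with at least 1 RPKM in at least 2 of the 6 libraries were tested (10958 genes). The fit held the mean of each group over all 6 libraries and no covariate, with an empirical Bayes estimate of the spread that follows the mean level (3 residual degrees of freedom, 3.70 prior degrees of freedom). The tests of genes and lists were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. Each of the 3 pairs of groups was compared. Fold changes are on the log2(RPKM + 1) scale unless called a ratio of RPKM, and the scale pulls changes of weakly expressed genes towards 0.

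34 gene lists written from general knowledge were tested as sets, of which 31 had at least 5 tested members. The lists cover genes linked to Evi1, glycolysis, gluconeogenesis, the pentose phosphate pathway, nucleotide synthesis, the tricarboxylic acid cycle, oxidative phosphorylation, mitochondrially encoded genes, antioxidants, hematopoietic stem cells, leukemia self-renewal, myeloid progenitors, neutrophils, monocytes and macrophages, dendritic cells, erythroid cells and megakaryocytes. They also cover mast cells with basophils and eosinophils, B-lymphoid cells, T and NK cells, stroma and endothelium, cell cycle, p53 targets, cell cycle inhibitors, TGF-beta signalling, interferon response, NF-kB and inflammation, immediate-early and stress genes, hypoxia, cholesterol and lipid synthesis, amino acid synthesis under Atf4, fatty acid oxidation, ribosomal proteins and sex-linked genes. Camera of limma was run with its preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and compares a list with all other genes. The lists, the groups, the tests and the rule for naming genes were chosen before the data were examined. The rule named Mecom and Fbp1, then the 8 genes with the largest rise and the 8 with the largest fall among those past the test with an absolute log2 fold change of at least 1 and no overlap between libraries (gene models without a name and antigen receptor segments left out). It also named up to 4 members with the smallest p of each list described. Epx, Fos, Nfkb2, Nr4a1, Relb, Txnip, and genes named beside a comparison for which the rule did not pick them, were chosen after their values were seen. Not every gene that the rule picked is reported here.

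The correlation and covariance of the comparisons with mock were set against 100 simulated draws of all 6 libraries in which no group differed. The test was tested on simulated data: of genes changed 2-fold it recovered 78%, 84% and 86% in the 3 comparisons. Of genes changed 4-fold it recovered 98%, 99% and 99%, with 12, 12 and 15 false calls. It made 0, 1 and 3 calls where nothing was changed. The simulated data gave every gene and library the same dispersion, whereas the mock pair differed more than the other pairs. These figures therefore hold for that setting and may not hold for the data. The alternatives tried were other pseudocounts, filters, scalings and estimates of the spread, a fit of the 4 libraries compared, the replicate number as a block, each library left out in turn, an estimated correlation in camera, and fry in place of camera. Array weights, voom on the implied reads and camera after other scalings were chosen after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.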

Results

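Messenger RNA was sequenced from bone marrow cells of C57BL/6 mice that had received marrow transduced with a vector, either with GFP alone (mock) or with the transcription factor Evi1 and GFP. The cells had been sorted for GFP, for absence of the markers of mature lineages and for the stem and progenitor receptor c-kit. The 6 libraries fall into 3 groups of 2: mock at 4 weeks after transplantation, Evi1 at 4 weeks (preleukemia) and Evi1 at 6 months (leukemia). The values are RPKM, read numbers scaled by the length of the transcript and by the total of the library. The totals recovered from the steps between low values were 21615558 and 20208302 reads for mock libraries 1 and 2. They were 16922992 and 21641740 for the preleukemia libraries and 21008139 and 19649055 for the leukemia libraries. At these totals 1 read on a gene of 1 kb was worth 0.0462 to 0.0591 RPKM, and between 10207 and 10551 rows reached 1 RPKM in a library. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

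The 3 groups separated on the first 2 principal components, which held 49.6% and 36.0% of the variance, and the third, with 8.17%, set mock library 1 apart from mock library 2. The mock pair differed more than the other pairs. The median absolute log2 difference between libraries was 0.22 in mock, 0.11 in preleukemia and 0.11 in leukemia, and the mean chi-square per gene was 54.6, 17.6 and 15.1. These exceeded the error of counting reads, so no pair was taken for 1 library deposited more than once, but the test covers that error alone and does not tell repeat preparations of 1 RNA from separate samples. Each library was counted as 1 sample, as the labels list them. There was no GFP group at 6 months, so time and leukemia differ together in both comparisons that include the leukemia libraries.

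**Figure D1:**
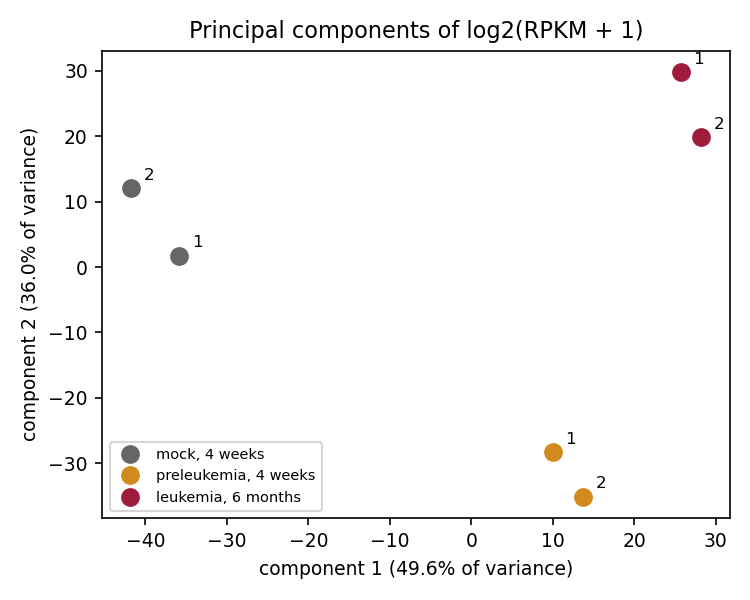
Scores of the 6 libraries on the first and second principal components of log2(RPKM + 1), which hold 49.6% and 36.0% of the variance, with each point 1 library numbered by replicate and coloured by group. The mock libraries lie at negative scores on component 1, and the preleukemia and leukemia libraries at positive scores on it and on opposite sides of 0 on component 2.

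Mecom, the gene that encodes Evi1, was measured first as a check of the labels. It lies on chromosome 3 at 29951296 to 30548008 of GRCm38 on the minus strand, a protein-coding gene with the identifier ENSMUSG00000027684.16. Its level was 0.789 ± 0.0216 RPKM in mock (SD, n = 2), 79.1 ± 1.49 in preleukemia and 66.6 ± 6.90 in leukemia, so that preleukemia stood 100.2-fold above mock as a ratio of mean RPKM. On the scale of log2(RPKM + 1) Mecom rose by 5.48 (SE 0.11, limma adjusted p = 6.37e-06) in preleukemia and by 5.24 (adjusted p = 4.34e-06) in leukemia. The leukemia and preleukemia groups differed by -0.25 (adjusted p = 0.157), which did not pass. Reads of the vector and of the mouse gene cannot be separated in these values. Fbp1, which encodes the gluconeogenic enzyme fructose-1,6-bisphosphatase, lies on chromosome 13 at 62864753 to 62888282 on the minus strand (ENSMUSG00000069805.10, protein coding). Its level rose from 2.04 ± 0.0422 RPKM in mock to 20.4 ± 1.28 in preleukemia and 56.9 ± 4.26 in leukemia (SD, n = 2 each). The implied read numbers were 76 and 69 in mock, 561 and 784 in preleukemia, and 2143 and 1803 in leukemia. The log2 fold changes of Fbp1 were 2.81 (SE 0.11, adjusted p = 9.42e-05) in preleukemia against mock, 4.25 (adjusted p = 9.04e-06) in leukemia against mock and 1.44 (adjusted p = 0.00121) in leukemia against preleukemia. Fbp1 had been chosen from knowledge of this study, so it is not independent evidence for the lists that hold it.

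**Figure D2:**
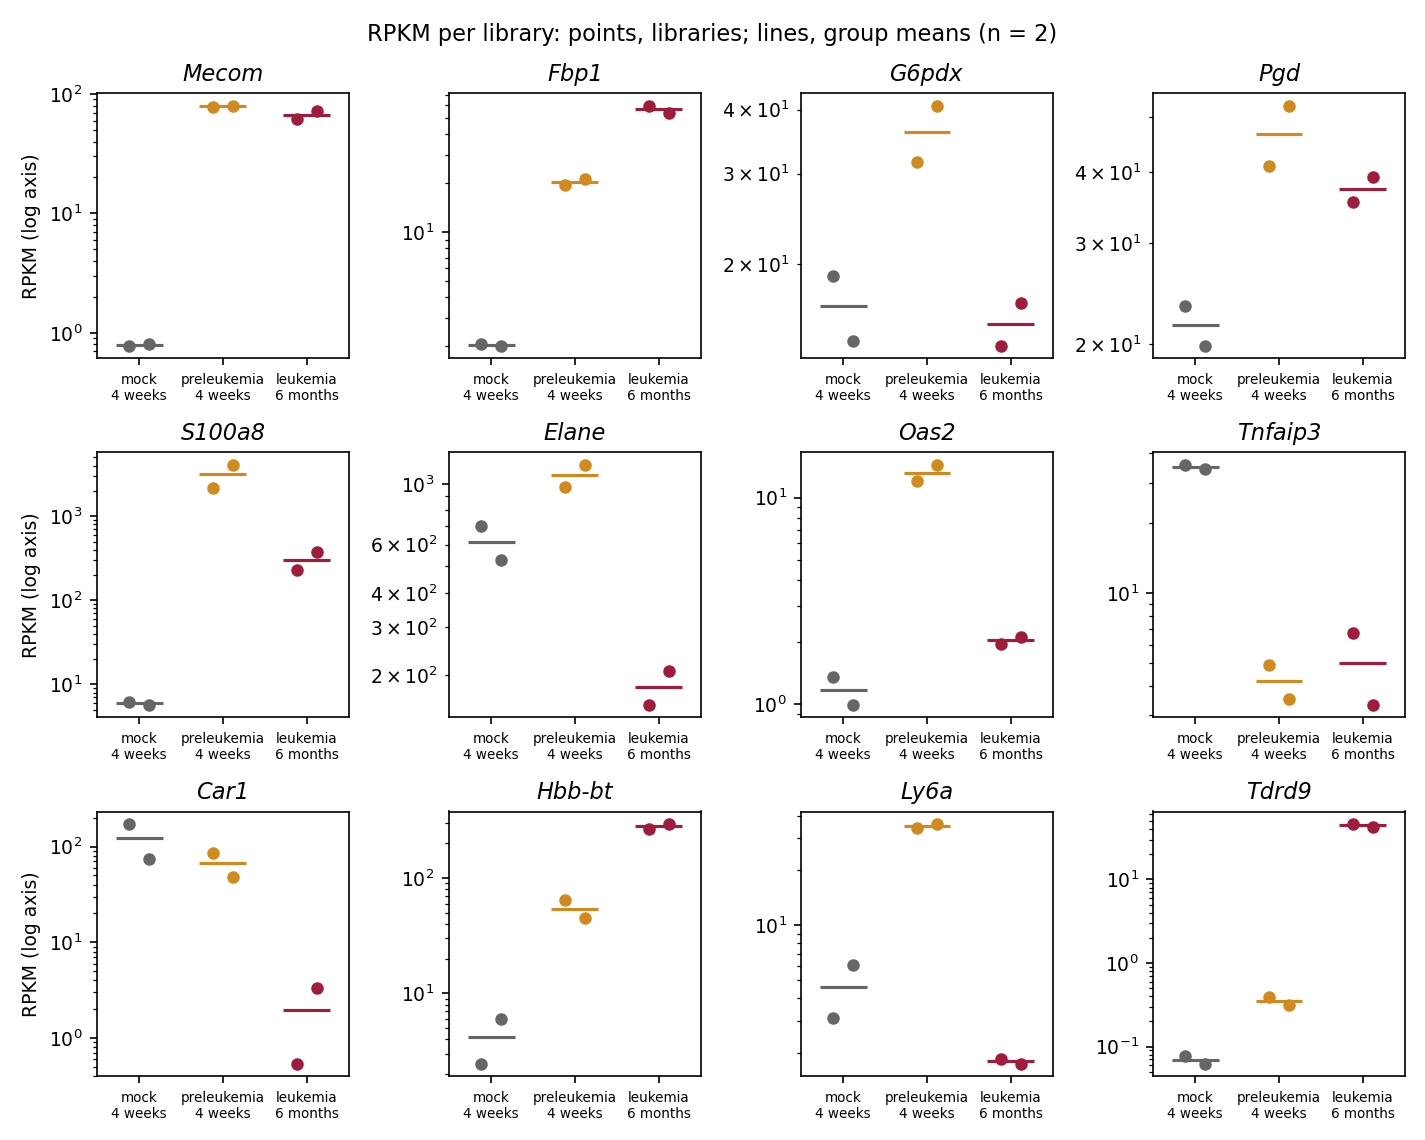
RPKM of 12 genes on a log axis, each with its own range, in mock and preleukemia at 4 weeks and leukemia at 6 months, where points are libraries and lines are group means (n = 2). Mecom rises from 0.789 to 79.1 and 66.6 RPKM, Fbp1 rises in both steps, S100a8 and Ly6a are highest in preleukemia, and Tdrd9 is high in leukemia with 44.6 RPKM.

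Evi1 cells were set against GFP cells at the same 4 weeks to ask which genes differ before leukemia. In preleukemia, the neutrophil and interferon lists were higher than in mock, and the NF-kB, B-lymphoid and mast cell lists were lower. These calls are by camera with its preset correlation, and no list passed with an estimated correlation. In fry the NF-kB list did not pass (fry adjusted p = 0.0899). S100a8, a subunit of the neutrophil protein calprotectin, rose from 5.97 ± 0.406 to 3148 ± 1370 RPKM (SD, n = 2), and Cst7, which encodes the protease inhibitor cystatin F, fell from 52.2 ± 12.3 to 0.320 ± 0.0554 RPKM. Of 10958 genes tested, 2140 changed in limma's moderated test at an adjusted p under 0.05, 1480 higher and 660 lower, and 702 of these by at least 1 on the log2 scale (463 higher, 239 lower). The share of changed genes that were higher was 69.2%, but 58.7% after TMM-like scaling and 52.9% after quantile normalization. Both libraries of one group lay above both of the other for 62.7% of genes, where chance gives 33.3%. The count was 3766 without mock library 1, 650 without preleukemia library 1, 463 without preleukemia library 2, 1395 without leukemia library 1 and 1394 without leukemia library 2. It was 1387 in a fit of the 4 libraries compared and 1421 with limma's array weights.

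Neutrophil genes showed the largest list median in preleukemia. Of 16 measured members 12 rose, none fell and 4 did not pass (13 rose adjusted over the list alone), with a median log2 fold change of 4.18. S100a9, the calprotectin partner of S100a8, rose from 3.49 ± 2.17 to 2261 ± 1114 RPKM (log2 fold change 8.97, adjusted p = 0.000208) and S100a8 by 8.75 (adjusted p = 9.42e-05). Chi3l3, a chitinase-like protein with near-identical copies that make its level uncertain, rose by 8.05 (adjusted p = 0.000403), and Lcn2, a lipocalin of the granules, from 1.12 ± 0.332 to 133 ± 101 RPKM (adjusted p = 0.00391). Padi4, which citrullinates histones, rose from 4.81 ± 0.942 to 48.4 ± 5.37 RPKM (adjusted p = 0.000183). The spread between the preleukemia libraries was large for part of these genes: library 2 held 9.58 times the RPKM of library 1 for Ltf (lactoferrin), 5.51 times for Ngp (neutrophilic granule protein) and 1.17 times for Padi4. Ngp rose by 7.18 (adjusted p = 0.00736) but did not pass without preleukemia library 2 (5.96, adjusted p = 0.0527). Clec4b2, a C-type lectin (5.76, adjusted p = 0.000183), and Chi3l1, another chitinase-like protein (5.46, adjusted p = 0.000203), were also among the 8 genes that rose most. Camera called the neutrophil list higher (adjusted p = 2.73e-08), and adjusted p = 0.645 with an estimated correlation.

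Of 16 myeloid progenitor genes measured, 8 rose, 1 fell and 7 did not pass (9 and 3 adjusted over the list alone), with a median of 0.67. Prtn3, which encodes proteinase 3 of the primary granules, rose from 366 ± 38.9 to 1014 ± 38.0 RPKM (log2 fold change 1.47, adjusted p = 0.000922). Csf3r, the receptor for granulocyte colony-stimulating factor, rose from 26.8 ± 6.53 to 73.7 ± 12.8 RPKM (1.44, adjusted p = 0.00434), and Igsf6 by 2.60 (adjusted p = 0.000632). The list passed in camera (adjusted p = 0.0260; adjusted p = 0.709 with an estimated correlation), but not without mock library 1 (adjusted p = 0.0582).

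Interferon-response genes rose as a group: 15 of 25 measured rose, none fell and 10 did not pass (17 rose and 1 fell adjusted over the list alone), with a median of 0.69. Oas2, an oligoadenylate synthetase of the antiviral response, rose from 1.17 ± 0.256 to 13.2 ± 1.75 RPKM (log2 fold change 2.71, adjusted p = 0.000311). Its relatives Oasl2 and Oas1a rose by 1.74 (adjusted p = 0.000892) and 1.71 (adjusted p = 0.00362), and Isg15, a ubiquitin-like modifier, from 2.62 to 8.28 RPKM (1.35, adjusted p = 0.00257). The camera adjusted p of the interferon list was 2.24e-05 (adjusted p = 0.645 with an estimated correlation).

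Enzymes of the pentose phosphate pathway, which makes NADPH and ribose phosphate, also rose: 8 of 13 measured rose and 5 did not pass (8 rose and 1 fell adjusted over the list alone), with a median of 0.47. Pgd, of the oxidative branch, rose from 21.6 ± 2.45 to 46.6 ± 8.01 RPKM (log2 fold change 1.07, adjusted p = 0.00513). G6pdx, which encodes the enzyme of the committing step, rose from 16.6 ± 3.34 to 36.2 ± 6.42 RPKM (1.08, adjusted p = 0.0104), and H6pd, its counterpart in the endoplasmic reticulum, by 1.24 (adjusted p = 0.00513). Without preleukemia library 2 neither passed (0.91, adjusted p = 0.0895 for G6pdx and 1.11, adjusted p = 0.0544 for H6pd). The pentose phosphate list passed in camera (adjusted p = 0.0394; adjusted p = 0.828 with an estimated correlation) but not without mock library 2 (adjusted p = 0.155) and not in fry (adjusted p = 0.114). Of 23 glycolysis genes 8 rose, 2 fell and 13 did not pass, the same adjusted over the list alone. The glycolysis list did not pass in camera (median 0.10, or 0.02 after quantile normalization, adjusted p = 0.286) but did in fry (adjusted p = 0.0446). Ldhb, a lactate dehydrogenase subunit, rose from 4.91 ± 0.449 to 77.3 ± 1.48 RPKM (3.73, adjusted p = 4.49e-05), Hk3, a hexokinase, by 1.78 (adjusted p = 0.000750), and Pkm, a pyruvate kinase, by 0.82 (adjusted p = 0.00395). Of 5 gluconeogenesis genes only Fbp1 rose (1 adjusted over the list alone). The list did not pass in camera (adjusted p = 0.274) but did in fry (adjusted p = 0.0446).

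NF-kB and inflammation genes were the list with the second smallest camera p. Of 16 measured, 9 fell, none rose and 7 did not pass (10 fell adjusted over the list alone), with a median of -1.51 (camera adjusted p = 9.67e-07; adjusted p = 0.645 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, fell from 35.1 ± 1.08 to 4.21 ± 1.00 RPKM (log2 fold change -2.80, adjusted p = 0.00169), and Nfkbia, another inhibitor, by 2.27 (adjusted p = 0.00213). The cytokine gene Tnf fell by 2.55 (adjusted p = 0.00100) and the chemokine gene Ccl4 by 1.98 (adjusted p = 0.00500). Among 17 immediate-early and stress genes 6 fell, none rose and 11 did not pass (7 fell and 1 rose adjusted over the list alone), with a median of -0.67. Egr1 fell from 46.6 ± 1.62 to 9.81 ± 1.79 RPKM (-2.15, adjusted p = 0.00144) and Jun from 206 ± 12.3 to 49.6 ± 21.5 RPKM (-2.10, adjusted p = 0.00435). Fos, at 278 RPKM in mock and 417 in preleukemia, did not pass (adjusted p = 0.0688). The immediate-early list passed (adjusted p = 0.00390; adjusted p = 0.645 with an estimated correlation) but not without preleukemia library 1 (adjusted p = 0.125). The mock libraries stood apart on part of these genes: Relb was at 0.857 and 14.9 RPKM, Nfkb2 at 8.31 and 42.3, and Nr4a1 at 45.9 and 226 in mock libraries 1 and 2.

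B-lymphoid, mast cell and dendritic cell lists were lower in preleukemia. Of 9 measured B-lymphoid genes 8 fell and 1 rose, the same adjusted over the list alone, with a median of -1.60 (camera adjusted p = 1.496e-05; adjusted p = 0.645 with an estimated correlation). Dntt, the template-independent polymerase of lymphoid precursors, fell from 16.0 ± 5.66 to 2.71 ± 0.411 RPKM (log2 fold change -2.16, adjusted p = 0.00251), and Igll1, a surrogate light chain gene, by 1.78 (adjusted p = 0.00194). In the mast cell, basophil and eosinophil list 6 of 11 fell, 1 rose and 4 did not pass (7 and 1 adjusted over the list alone), with a median of -0.79 (adjusted p = 0.000748; adjusted p = 0.645 with an estimated correlation). Without mock library 1 this list did not pass (adjusted p = 0.0912). Hdc, the histamine-forming decarboxylase, fell from 11.4 ± 3.85 to 0.941 ± 0.0824 RPKM (-2.64, adjusted p = 0.00109), and Cpa3, the mast cell carboxypeptidase, from 30.8 ± 14.8 to 4.94 ± 0.956 (-2.35, adjusted p = 0.00434). The gene that rose was Epx, eosinophil peroxidase (adjusted p = 0.0375). Of 7 dendritic cell and MHC class II genes 3 fell and 4 did not pass, the same adjusted over the list alone (median -1.07, adjusted p = 0.00139; adjusted p = 0.645 with an estimated correlation). The dendritic list did not pass without mock library 2 (adjusted p = 0.0519). Flt3, a receptor of lymphoid and dendritic progenitors, fell by 2.00 (adjusted p = 0.00741) and by 1.91 without preleukemia library 2, which did not pass (adjusted p = 0.0664). Other genes among the 8 that fell most were Cnn3, a calponin (22.2 ± 0.146 to 1.23 ± 0.0488 RPKM, -3.38, adjusted p = 9.42e-05), Cd69, an activation antigen (-3.13, adjusted p = 0.000297), and Pdgfrb, a growth factor receptor of stromal cells (-2.88, adjusted p = 0.000262).

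5 further lists passed in camera as lower, with smaller medians. TGF-beta signalling had 6 of 16 genes lower, 1 higher and 9 that did not pass, the same adjusted over the list alone (median -0.41, adjusted p = 0.00372; adjusted p = 0.645 with an estimated correlation). Of 13 mitochondrially encoded genes 2 fell (0 adjusted over the list alone) and 11 did not pass, with a median of -0.46 (adjusted p = 0.00122; adjusted p = 0.716 with an estimated correlation). Of 18 amino acid synthesis genes 5 fell, 1 rose and 12 did not pass (6 and 2 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.00943; adjusted p = 0.645 with an estimated correlation; 0.0519 without mock library 2). Nucleotide synthesis had 2 of 28 genes lower and 1 higher (1 and 1 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.0102; adjusted p = 0.828 with an estimated correlation; 0.272 without mock library 1). Of 30 ribosomal protein genes 1 fell (0 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.00943; adjusted p = 0.828 with an estimated correlation). It did not pass without mock library 2 (0.0772) or preleukemia library 2 (0.0687), and its median was -0.21 after quantile normalization. Among the lists that did not pass, 7 of 17 hematopoietic stem cell genes rose and 2 fell, the same adjusted over the list alone (median 0.26, or 0.15 after quantile normalization, adjusted p = 0.113), where Mecom is one of the 7. Of 23 genes linked to Evi1, 6 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.320), among them Itga6, an integrin that rose by 0.90 (adjusted p = 0.00319). In fry the stem cell list (adjusted p = 0.0211) and the Evi1-linked list (adjusted p = 0.0338) passed as higher.

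**Figure D3:**
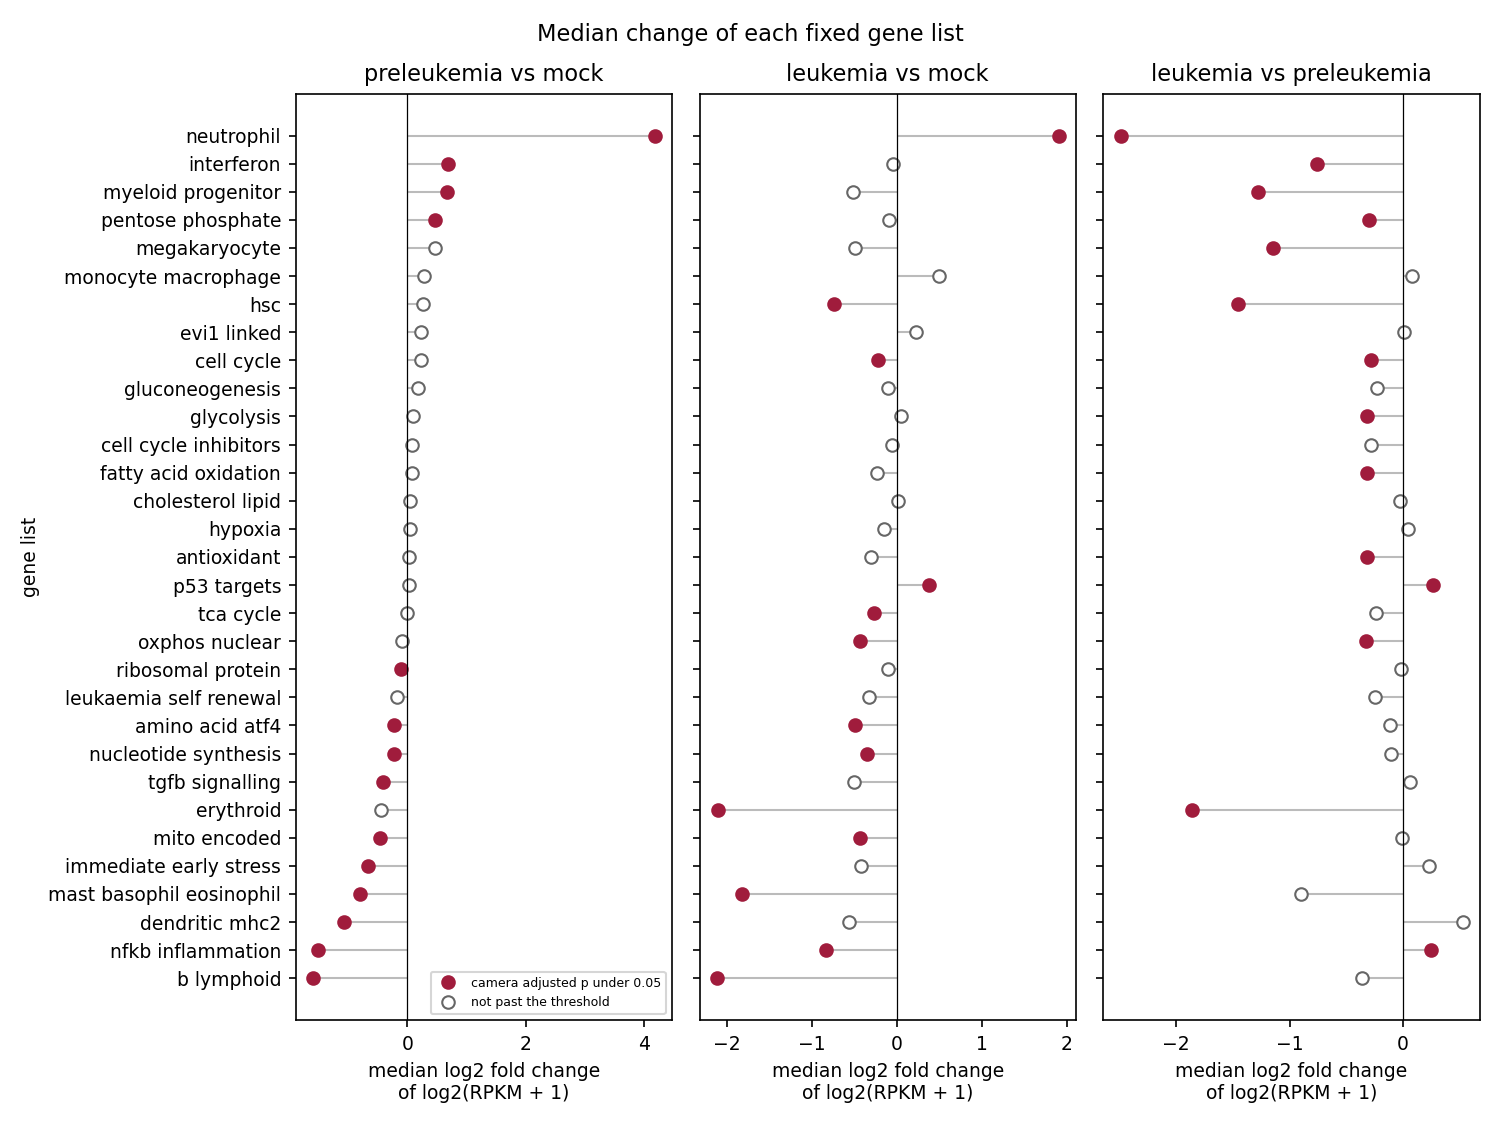
Median log2 fold change, on the log2(RPKM + 1) scale, of the measured members of each of 31 gene lists in the 3 comparisons, with lists past a camera adjusted p of 0.05 as filled points and the others as open points. The neutrophil list has a median of 4.18 in preleukemia against mock, 1.91 in leukemia against mock and -2.49 in leukemia against preleukemia.

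Leukemia cells at 6 months were then set against GFP cells at 4 weeks. The erythroid, B-lymphoid, mast cell and oxidative phosphorylation lists were lower in leukemia, and the neutrophil list was higher, by camera with its preset correlation. With an estimated correlation no list passed. In fry the erythroid (fry adjusted p = 0.0648), oxidative phosphorylation (0.0642) and neutrophil (0.0642) lists did not pass. Car1, an erythroid carbonic anhydrase, fell from 124 ± 71.3 to 1.94 ± 1.99 RPKM (SD, n = 2; log2 fold change -5.47, adjusted p = 0.00162). Npy, which encodes neuropeptide Y, rose from 0.0437 ± 0.0618 to 77.0 ± 3.02 RPKM (6.22, adjusted p = 3.99e-06). Tdrd9, a gene of the piRNA pathway on chromosome 12 at 111971559 to 112068854, rose from 0.0694 ± 0.0108 to 44.6 ± 2.93 RPKM (5.41, adjusted p = 7.71e-06). In limma's test 2809 of 10958 genes changed, 1328 higher and 1481 lower, and 895 of these by at least 1 on the log2 scale (399 higher, 496 lower). The share of changed genes that were higher was 47.3%, but 50.7% after TMM-like scaling and 53.4% after quantile normalization, and without mock library 1 there were 1890 higher and 1807 lower. The groups did not overlap for 65.4% of genes, where chance gives 33.3%. The count was 1005 without leukemia library 1 and 980 without leukemia library 2.

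Erythroid genes fell together in leukemia: 14 of 17 measured fell, 1 rose and 2 did not pass (15 and 1 adjusted over the list alone), with a median of -2.11 (camera adjusted p = 4.16e-05; adjusted p = 0.708 with an estimated correlation). Car2, another carbonic anhydrase, fell from 88.8 ± 52.0 to 2.42 ± 0.562 RPKM (log2 fold change -4.59, adjusted p = 0.000947), and Blvrb, biliverdin reductase B, by 2.79 (adjusted p = 0.00231). Aqp1, the water channel of red cells, which is outside the list, fell by 5.03 (adjusted p = 0.000326). The member that rose was Hbb-bt, a beta-globin gene on chromosome 7 at 103812524 to 103813996, from 4.21 ± 2.51 to 282 ± 22.2 RPKM (5.85, adjusted p = 0.000206). Its near-identical neighbour Hbb-bs stood at 2.34 ± 0.425 and 0.844 ± 0.725 RPKM, and reads shared by the pair make both levels uncertain.

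B-lymphoid genes were lower as well, with 8 of 9 lower and 1 higher, the same adjusted over the list alone (median -2.12, camera adjusted p = 0.000120; adjusted p = 0.708 with an estimated correlation). Dntt fell from 16.0 ± 5.66 to 0.0120 ± 0.0169 RPKM (log2 fold change -4.03, adjusted p = 0.000237), and Vpreb1, a surrogate light chain gene, by 2.46 (adjusted p = 0.00173). Of 11 mast cell, basophil and eosinophil genes 8 fell and 3 did not pass, the same adjusted over the list alone (median -1.83, adjusted p = 0.000267; adjusted p = 0.708 with an estimated correlation). Cpa3 fell by 3.98 (adjusted p = 0.000544) and Gzmb, the granule protease granzyme B, by 3.49 (adjusted p = 0.000427). The neutrophil list was above mock: 7 of 16 rose, none fell and 9 did not pass, the same adjusted over the list alone (median 1.91, adjusted p = 0.000210; adjusted p = 0.708 with an estimated correlation). S100a9 rose by 5.72 (adjusted p = 0.000623), Padi4 from 4.81 ± 0.942 to 56.2 ± 3.63 RPKM (3.31, adjusted p = 7.82e-05) and Cxcr2, a neutrophil chemokine receptor, by 2.63 (adjusted p = 0.000234). Olfm4, a granule protein outside the list, rose by 4.98 (adjusted p = 0.00148).

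Nuclear genes of oxidative phosphorylation had the smallest camera p in leukemia against mock: 17 of 32 measured fell and 15 did not pass (25 fell adjusted over the list alone). The median was -0.43 (adjusted p = 1.13e-05; adjusted p = 0.708 with an estimated correlation). Cyc1, a subunit of complex III, fell from 55.2 ± 2.78 to 36.5 ± 0.925 RPKM (log2 fold change -0.58, adjusted p = 0.00581; -0.56 and 0.0569 without leukemia library 2). Of 24 genes of the tricarboxylic acid cycle 7 fell, 1 rose and 16 did not pass, the same adjusted over the list alone (median -0.26, adjusted p = 0.0238; adjusted p = 0.708 with an estimated correlation). The list did not pass without mock library 1 (0.229) or leukemia library 2 (0.0912). Nucleotide synthesis had 8 of 28 genes lower (9 adjusted over the list alone) and a median of -0.35 (adjusted p = 0.00608; adjusted p = 0.708 with an estimated correlation; 0.0515 without mock library 1). Impdh1, which makes a guanine nucleotide precursor, fell from 23.9 ± 4.85 to 7.17 ± 1.48 RPKM (-1.61, adjusted p = 0.00175). Of 18 amino acid synthesis genes 7 fell, 1 rose and 10 did not pass (9 and 1 adjusted over the list alone), with a median of -0.50 (adjusted p = 0.0188; adjusted p = 0.708 with an estimated correlation; 0.0710 without mock library 2). Asns, asparagine synthetase, fell from 6.23 ± 2.00 to 0.180 ± 0.00851 RPKM (-2.59, adjusted p = 0.000720).

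In the glycolysis list 3 genes of 23 rose, 6 fell and 14 did not pass (3 and 7 adjusted over the list alone), and its median of 0.04, or 0.07 after quantile normalization, and its mean of -0.07 differed in sign (adjusted p = 0.977). Ldhb rose by 2.77 (adjusted p = 5.89e-05) and Hk3 rose from 63.6 to 181 RPKM (adjusted p = 0.000825), while Pgam1, a phosphoglycerate mutase, fell by 1.07 (adjusted p = 0.00137) and Pklr, the pyruvate kinase of red cells and liver, by 2.99 (adjusted p = 0.00388). Of 13 pentose phosphate genes 1 rose and 2 fell, the same adjusted over the list alone, and the list did not pass (median -0.09, or -0.04 after quantile normalization, adjusted p = 0.748). The gene that rose was Pgd, from 21.6 ± 2.45 to 37.4 ± 2.69 RPKM (0.77, adjusted p = 0.0119), but did not pass without leukemia library 1 (0.84, adjusted p = 0.0518) or leukemia library 2 (0.70, adjusted p = 0.0833). G6pdx stood at 16.6 ± 3.34 and 15.3 ± 2.07 RPKM (-0.10, adjusted p = 0.723). In the gluconeogenesis list only Fbp1 of 5 genes rose (1 adjusted over the list alone; adjusted p = 0.498), and the median of -0.11, or -0.04 after quantile normalization, differed in sign from the mean of 0.74 and from the test.

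Stem cell genes fell on balance: of 17 measured 10 fell, 3 rose and 4 did not pass, the same adjusted over the list alone (median -0.75, camera adjusted p = 0.0258; adjusted p = 0.708 with an estimated correlation). The list did not pass without mock library 1 (0.0722) or mock library 2 (0.0710). Ifitm1, an interferon-induced membrane protein with close relatives, fell from 34.8 ± 2.42 to 1.09 ± 0.497 RPKM (log2 fold change -4.12, adjusted p = 7.82e-05). Hlf, a transcription factor of stem cells, stood at 2.53 ± 0.0596 RPKM in mock and was listed at 0 in both leukemia libraries (adjusted p = 0.00129). The 3 that rose were Mecom, Robo4, a guidance receptor (1.99, adjusted p = 0.00110), and Txnip, an inhibitor of thioredoxin (1.44, adjusted p = 0.0109). Of 23 genes linked to Evi1 7 rose and 3 fell (8 and 3 adjusted over the list alone), and the list did not pass (median 0.23, adjusted p = 0.0844). Erg, a transcription factor of stem cells, rose from 20.4 ± 0.904 to 47.2 ± 4.63 RPKM (1.17, adjusted p = 0.000940), and Gpr56, an adhesion receptor, by 1.35 (adjusted p = 0.00203).

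Of 17 p53 targets 6 rose, none fell and 11 did not pass (6 rose and 1 fell adjusted over the list alone), with a median of 0.38 (adjusted p = 0.0467; adjusted p = 0.708 with an estimated correlation). The p53 list did not pass without mock library 1 (0.388) or leukemia library 2 (0.0630), nor after TMM-like scaling (0.0562) or quantile normalization (0.0575). Trp53inp1, a stress-induced nuclear protein, rose from 4.81 ± 0.00100 to 15.6 ± 2.20 RPKM (log2 fold change 1.51, adjusted p = 0.000961), Sesn1, a sestrin, by 1.26 (adjusted p = 0.00351) and Phlda3 by 1.33 (adjusted p = 0.00321). The NF-kB list was lower than in mock, with 7 of 16 lower, 2 higher and 7 that did not pass, the same adjusted over the list alone (median -0.83, adjusted p = 0.0440; adjusted p = 0.708 with an estimated correlation). Tnfaip3 fell by 2.64 (adjusted p = 0.00146) and Nfkbia by 2.11 (adjusted p = 0.00185). The NF-kB list did not pass without mock library 2 (0.859) or leukemia library 2 (0.0551). Relb, one of its members, stood at 0.857 and 14.9 RPKM in mock libraries 1 and 2. Of 29 cell cycle genes 8 fell and 21 did not pass, the same adjusted over the list alone (median -0.22, adjusted p = 0.0258; adjusted p = 0.746 with an estimated correlation). This call was lost without mock library 1 (0.883) or leukemia library 2 (0.133). Of 13 mitochondrially encoded genes 2 fell (1 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.0237; adjusted p = 0.708 with an estimated correlation). That call was lost without mock library 1 (0.0738), mock library 2 (0.0969) or leukemia library 1 (0.0781), and after quantile normalization (0.0548).

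Leukemia was set against preleukemia to follow the Evi1 cells from 4 weeks to 6 months. The myeloid progenitor, megakaryocyte, erythroid, stem cell, interferon and oxidative phosphorylation lists were lower in leukemia than in preleukemia, and p53 targets were higher, by camera with its preset correlation. Again no list passed with an estimated correlation. In fry the erythroid (fry adjusted p = 0.0713) and oxidative phosphorylation (0.0757) lists did not pass. Elane, neutrophil elastase, fell from 1074 ± 144 to 181 ± 36.4 RPKM (SD, n = 2; log2 fold change -2.57, adjusted p = 0.00139), and Pf4, a platelet chemokine, from 37.3 ± 9.02 to 0.261 ± 0.368 RPKM (-4.94, adjusted p = 0.000265). Tdrd9 rose from 0.355 ± 0.0538 to 44.6 ± 2.93 RPKM (5.07, adjusted p = 3.57e-05), Mrc2, a collagen receptor, by 3.78 (adjusted p = 0.000110) and Npy by 3.48 (adjusted p = 9.66e-05). Ccl3, an inflammatory chemokine, rose from 9.40 ± 3.69 to 86.1 ± 6.88 RPKM (3.11, adjusted p = 0.00236). In limma's test 2006 of 10958 genes changed, 578 higher and 1428 lower, and 679 of these by at least 1 on the log2 scale (165 higher, 514 lower). The share of higher genes was 28.8%, but 42.1% after TMM-like scaling and 50.8% after quantile normalization, which shifted the median log2 fold change of all genes by 0.12. The groups did not overlap for 70.7% of genes, where chance gives 33.3%. The count moved with each library: 3447 and 3453 without mock library 1 or 2, 660 and 404 without preleukemia library 1 or 2, and 449 and 815 without leukemia library 1 or 2. It was 3419 in a fit of the 4 libraries compared, 3786 with array weights and 1302 with no filter.

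Genes of myeloid progenitors fell: 10 of 16 measured fell, none rose and 6 did not pass (13 fell and 1 rose adjusted over the list alone), with a median of -1.28 (camera adjusted p = 0.000174; adjusted p = 0.663 with an estimated correlation). Prtn3 fell from 1014 ± 38.0 to 251 ± 8.07 RPKM (log2 fold change -2.01, adjusted p = 0.000502), Ms4a3, a marker of granulocyte and monocyte progenitors, by 2.51 (adjusted p = 0.00326) and Ctsg, cathepsin G, by 1.29 (adjusted p = 0.00422). In the neutrophil list 9 of 16 fell, none rose and 7 did not pass (11 and 1 adjusted over the list alone), with a median of -2.49 (adjusted p = 0.00364; adjusted p = 0.663 with an estimated correlation). S100a8 fell from 3148 ± 1370 to 300.0 ± 103 RPKM (-3.36, adjusted p = 0.00236) and S100a9 by 3.25 (adjusted p = 0.00594), while Padi4 did not pass (0.22, adjusted p = 0.344).

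Stem cell genes were lower than in preleukemia, with 11 of 17 lower, 2 higher and 4 that did not pass (13 and 2 adjusted over the list alone). The median was -1.45 (adjusted p = 0.000174; adjusted p = 0.663 with an estimated correlation). Ly6a, which encodes the surface antigen Sca-1 and has close relatives, fell from 35.1 ± 1.54 RPKM to 1.86 and 1.74 RPKM in the leukemia libraries (log2 fold change -3.69, adjusted p = 0.000812). Mycn, a Myc-family factor, fell by 2.66 (adjusted p = 0.00164) and Ifitm3 from 214 ± 1.29 to 38.1 ± 1.89 RPKM (-2.46, adjusted p = 0.000110). Of 17 megakaryocyte genes 10 fell, 2 rose and 5 did not pass, the same adjusted over the list alone (median -1.15, adjusted p = 0.00505; adjusted p = 0.663 with an estimated correlation). Ppbp, another platelet chemokine, fell by 2.79 (adjusted p = 0.00114) and F2r, the thrombin receptor, by 2.05 (adjusted p = 0.00193), whereas Selp, P-selectin, rose from 22.5 ± 4.69 to 64.6 ± 2.02 RPKM (1.49, adjusted p = 0.00233). Of 17 erythroid genes 11 fell, 1 rose and 5 did not pass (12 and 1 adjusted over the list alone), with a median of -1.86 (adjusted p = 0.000205; adjusted p = 0.663 with an estimated correlation). Car1 fell by 4.67 (adjusted p = 0.00424) and Hbb-bs by 3.72 (adjusted p = 0.000994), and Hbb-bt rose by 2.37 (adjusted p = 0.00569; 2.12 and 0.0533 without preleukemia library 2).

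Interferon-response genes fell back from their preleukemia level, with 13 of 25 lower, 2 higher and 10 that did not pass (17 and 2 adjusted over the list alone). The median was -0.76 (adjusted p = 0.000174; adjusted p = 0.663 with an estimated correlation). Oas2 fell from 13.2 ± 1.75 to 2.04 ± 0.112 RPKM (log2 fold change -2.22, adjusted p = 0.000937), Isg15 by 1.41 (adjusted p = 0.00264) and Irf7, a transcription factor of the response, by 1.15 (adjusted p = 0.00486). Against mock, 3 interferon genes of 25 rose in leukemia and 1 fell (2 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.554).

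Several metabolic lists were lower in leukemia than in preleukemia, with smaller medians after quantile normalization: -0.19 for oxidative phosphorylation, -0.19 for the pentose phosphate pathway, -0.17 for glycolysis, -0.21 for fatty acid oxidation and -0.20 for antioxidants. Of 32 oxidative phosphorylation genes 10 fell and 22 did not pass (13 fell adjusted over the list alone), with a median of -0.33 (adjusted p = 0.000174; adjusted p = 0.663 with an estimated correlation). Pentose phosphate genes had 5 of 13 lower and 8 that did not pass, the same adjusted over the list alone, with a median of -0.30 (adjusted p = 0.00553; adjusted p = 0.663 with an estimated correlation). G6pdx fell from 36.2 ± 6.42 to 15.3 ± 2.07 RPKM (log2 fold change -1.18, adjusted p = 0.00833), but did not pass without preleukemia library 2 (-1.01, adjusted p = 0.0748) or leukemia library 1 (-1.05, adjusted p = 0.0651). H6pd fell by 1.17 (adjusted p = 0.00663), and likewise did not pass without preleukemia library 2 (-1.04, adjusted p = 0.0675) or leukemia library 1 (-1.16, adjusted p = 0.0538). Pgd did not pass (-0.30, adjusted p = 0.198). Of 23 glycolysis genes 8 fell and 15 did not pass (10 fell adjusted over the list alone), with a median of -0.32 (adjusted p = 0.0253; adjusted p = 0.663 with an estimated correlation; 0.0713 without preleukemia library 2). Ldhb fell by 0.96 (adjusted p = 0.00321). Of 18 fatty acid oxidation genes 3 fell, the same adjusted over the list alone (median -0.31, adjusted p = 0.0239; adjusted p = 0.663 with an estimated correlation). Etfb, an electron transfer subunit, fell from 95.4 ± 4.84 to 36.1 ± 1.92 RPKM (-1.38, adjusted p = 0.00200). Of 18 antioxidant genes 5 fell (8 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.0442; adjusted p = 0.663 with an estimated correlation). That call was lost without mock library 1 (0.0592), mock library 2 (0.0566) or preleukemia library 1 (0.0855). Gstm1, a glutathione transferase with close relatives, fell by 1.34 (adjusted p = 0.00297).

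Of 17 p53 targets 6 rose, 1 fell and 10 did not pass, the same adjusted over the list alone (median 0.26, adjusted p = 0.00228; adjusted p = 0.663 with an estimated correlation). Pmaip1, a pro-apoptotic gene, rose from 7.29 ± 1.52 to 53.1 ± 10.04 RPKM (log2 fold change 2.71, adjusted p = 0.00615), and Phlda3 from 0.418 ± 0.213 to 3.85 ± 0.175 RPKM (1.78, adjusted p = 0.00236). NF-kB genes were higher, with 3 of 16 higher and 13 that did not pass (4 higher adjusted over the list alone), and a median of 0.25, or 0.37 after quantile normalization (adjusted p = 0.00816; adjusted p = 0.663 with an estimated correlation). Ccl3 and Ccl4 were 2 of the 3, and Ccl4 rose from 3.35 ± 1.70 to 17.4 ± 3.55 RPKM (2.12, adjusted p = 0.00438). In the cell cycle list 1 gene of 29 fell and 28 did not pass, the same adjusted over the list alone (median -0.28, or -0.14 after quantile normalization, adjusted p = 0.0405; adjusted p = 0.785 with an estimated correlation). The call was lost without preleukemia library 2 (0.0761) or leukemia library 2 (0.348). For the genes linked to Evi1, 6 of 23 rose and 2 fell (6 and 4 adjusted over the list alone; adjusted p = 0.105, which fell to 0.0485 without preleukemia library 2 and 0.0275 without leukemia library 1), with a median of 0.01, or 0.16 after quantile normalization, and a mean of -0.02. In the gluconeogenesis list only Fbp1 of 5 rose (1 adjusted over the list alone; adjusted p = 0.629), with a median of -0.23, or -0.12 after quantile normalization, and a mean of 0.10.

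Both Evi1 groups were compared with the same mock libraries. 642 genes were higher in both and 441 lower in both, among them Mecom, Fbp1, S100a8, Ldhb and Padi4 as higher and Cst7, Tnfaip3 and Dntt as lower. Another 56 went opposite ways. Independent lists of these sizes would share 179.4 higher and 89.2 lower genes. The log2 fold changes correlated across genes with r = 0.624 (0.499 on average over 100 simulated draws of all 6 libraries in which no group differed), and their covariance was 0.244 (simulated 0.0160, a difference of 0.228), where genes are not independent replicates. The mock libraries were too few to split, so part of the excess over independent lists may come from the shared controls. The simulated covariance includes these controls, but with the same spread in each group. As the mock pair differed more than the other pairs, the part due to shared controls may be larger than simulated. The 1083 genes changed the same way became 2068 without mock library 1, 371 and 319 without preleukemia library 1 or 2, and 513 and 446 without leukemia library 1 or 2.

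Of the 1480 genes higher in preleukemia than in mock, 579 were lower in leukemia than in preleukemia, 69 were higher still and 832 did not pass. Elane, Prtn3, Oas2, Ly6a and Pf4 were among the 579, and Fbp1 and Hbb-bt among the 69. Of the 660 genes lower in preleukemia, 104 were higher in leukemia, Ccl3 and Ccl4 among them, 76 were lower still and 480 did not pass. Both comparisons share the preleukemia libraries, whose chance values enter them with opposite signs, and the counts were not set against a value for no change.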

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

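The tests of a fixed makeup, of depth, of carried-over erythroid cells, of shared reads, of a library deposited more than once and of deeper sequencing were chosen only after the result was seen.

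12 genes named for a comparison moved in opposite directions against mock in the Evi1 groups, with all 3 comparisons past limma's adjusted p of 0.05. A gene that passes in opposite directions against mock is nearly bound to differ between leukemia and preleukemia, so that call is no separate support. 10 were higher than mock in preleukemia and lower in leukemia. Granule and progenitor genes were Elane (leukemia against preleukemia -2.57, with 0.82 and -1.75 against mock), Prtn3 (-2.01, with 1.47 and -0.54) and Ms4a3 (-2.51, with 1.31 and -1.20). Members of the stem cell list were Ly6a (-3.69, with 2.75 and -0.94), Mycn (-2.66, with 1.504 and -1.16) and Ifitm3 (-2.46, with 1.96 and -0.50). The others were the platelet chemokine Pf4 (-4.94, with 1.73 and -3.20), the globin gene Hbb-bs (-3.72, with 2.81 and -0.91), the glutathione transferase Gstm1 (-1.34, with 0.75 and -0.60) and the interferon regulator Irf7 (-1.15, with 0.58 and -0.56). The interferon list also rose in preleukemia against mock (median 0.69) and fell in leukemia against preleukemia (-0.76). Whether Ly6a and Ifitm3 changed with that list and not as stem cell genes was not tested. Ccl3 (3.11, with -1.68 and 1.43) and Gem, a small GTPase (2.84, with -1.52 and 1.31), were lower than mock in preleukemia and higher in leukemia. With any 1 library left out the 12 kept their signs in all 3 comparisons, which their choice by passing calls made nearly certain. All 3 calls held for 7 and 7 genes without mock library 1 or 2, 3 and 5 without preleukemia library 1 or 2, 2 and 4 without leukemia library 1 or 2, and 1, Pf4, throughout. Hbb-bs passed against mock in leukemia by an adjusted p of 0.0458, and reads shared with Hbb-bt make its level uncertain. Time and leukemia differ together between the Evi1 groups, and neither was tested apart from the other.

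Neutrophil genes were higher in preleukemia than in mock, with a list median of 4.18, and a difference in depth between the groups is argued against by the totals, as the 20208302 reads of mock library 2 lie between the 16922992 and 21641740 of the preleukemia libraries. An admixed population of fixed makeup at different shares in the 2 preleukemia libraries was also considered. It would keep 1 ratio between the libraries only if the other sorted cells lacked these genes. The log2 ratio spanned 1.84 between the percentiles 10 and 90 of 9 neutrophil genes at 10 RPKM or more. As the level of these genes in the other sorted cells is not known, the span cannot decide for or against such a population. Late-stage neutrophils carried through the sort, which selected c-kit and against lineage markers, remain open: 8 tested of 17 listed late-stage genes had a median of 0.63, between the limits set, and 2 passed, Mmp9 and Cxcr2. Of the 17, 5 are also in the neutrophil list, Retnlg, Mmp8, Mmp9, Ly6g and Cxcr2, and Cxcr2's value had been seen. All 5 are among the 8 tested and include both that passed, so they are no separate support. The tested genes outside that list, Asprv1, Mxd1 and Slpi, changed by 0.48, -0.12 and -0.26 and did not pass. Slpi, the most abundant, stood at 23.7 and 28.4 RPKM in mock and 20.6 and 22.4 in preleukemia. Preleukemia libraries 1 and 2 held 2.74 and 15.5 RPKM of Mmp9, 0.352 and 8.53 of Ly6g, 0.583 and 3.57 of Retnlg and 0.0482 and 2.96 of Mmp8. An effect of Evi1 on granulocytic maturation may be a hypothesis and was not tested.

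Hbb-bt rose in leukemia, with 266 and 298 RPKM against 2.44 and 5.98 in mock. Erythroid cells or hemoglobin RNA carried over would bring alpha-globin along, but Hba-a1 and Hba-a2 together reached at most 0.0203 of the Hbb-bt level in leukemia, against at least 0.633 in the other libraries. Reads shared with the near-identical Hbb-bs would keep 1 ratio between the genes, but the lowest leukemia ratio of Hbb-bt to Hbb-bs was 76.1 times the highest in the other libraries. Activation of the surrounding region may be the cause and remains open: 0 of 1 tested gene within 200 kb rose, which is too few. That gene, Hbb-bs, fell against mock (log2 fold change -0.91, limma adjusted p = 0.0458). The untested genes there stood at or below 0.0829 RPKM in leukemia.

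8 genes, chosen after their values were seen, had at least 5 RPKM in both leukemia libraries and a mean under 1 in each other group. Tdrd9, Camkv, a pseudokinase, Mrc2 and Capn11, a calpain, were among them. A library deposited more than once is argued against by a mean chi-square of 15.1 per gene between the leukemia libraries, and deeper sequencing by totals of at most 21008139 reads in leukemia against 21641740 in the deepest other library. Activation of whole regions may be a cause and remains open: 50% of the 8 had a neighbour within 200 kb that also rose, against 21.5% of random genes with as many neighbours (one-sided p = 0.0608 by permutation, 10000 draws). Of the 8, 1700006J14Rik and Msrb3 both lie on chromosome 10, at 120364157 to 120384336 and 120781096 to 120899101. The gap between them exceeds 200 kb, so neither was counted as a risen neighbour of the other. Whether random genes lie as close to each other as often was not tested. An outgrowth by 6 months of cells with changes in the 8 genes was not tested.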

How the results depend on the processing

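Array weights, voom on implied reads and the scalings of camera were chosen only after the result was seen. No gene called in a comparison changed sign in any alternative, which having passed the test made likely beforehand. The 2140 genes changed in preleukemia against mock became 1387 in a fit of the 4 libraries compared, 1421 with array weights and 702 with a log2 fold change of at least 1. The 2809 of leukemia against mock became 895 with that limit. The 2006 of leukemia against preleukemia became 3419 with 4 libraries, 3786 with array weights, 1302 with no filter, which tests more genes, and 679 with the limit. The 1083 genes changed alike against mock became 676, 710 and 326 with 4 libraries, array weights and the limit. Leaving out 1 library gave 463 to 3766, 980 to 3697 and 404 to 3453 genes in the 3 comparisons and 319 to 2068 changed alike, where the lone sample is assumed to vary like the other groups. The mock pair was the farthest apart and had an array weight of 0.422 against 1.52 and 1.56. The cause of the other changes was not tested.

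The 14, 13 and 14 gene lists past camera became 0, 0 and 0 with an estimated correlation. Leaving out 1 library gave 10 to 14, 8 to 13 (8 without mock library 1) and 14 to 18. With the replicate number as a block 2118, 2932 and 2060 genes, 13, 13 and 13 lists and 1093 genes changed alike passed, and the block ended the calls of the pentose phosphate list in preleukemia against mock (0.0563) and of antioxidants in leukemia against preleukemia (0.0535). Deviations of libraries with the same number correlated by 0.116, 0.0125 and 0.179, so the numbers were not read as pairs. The oxidative phosphorylation list in preleukemia against mock (adjusted p = 0.0884) passed after TMM-like scaling (0.0222) and quantile normalization (0.0478), and the ribosomal list in leukemia against preleukemia (0.522) after quantile normalization (0.0197). Fry, which does not compare a list with other genes, passed 8, 7 and 7 lists. Of camera's calls it kept only neutrophil, mast cell, B-lymphoid and interferon in preleukemia against mock. In leukemia against mock it kept only mast cell, B-lymphoid, p53 targets and amino acid synthesis. In leukemia against preleukemia it kept only stem cell, myeloid progenitor, megakaryocyte, p53 targets and interferon. The other lists that fry passed were not called by camera. In preleukemia against mock these were stem cells, genes linked to Evi1, glycolysis and gluconeogenesis, all higher. In leukemia against mock they were genes linked to Evi1 (fry adjusted p = 0.0145) and gluconeogenesis (0.0240), higher, and leukemia self-renewal, lower. In leukemia against preleukemia they were leukemia self-renewal and cell cycle inhibitors, both lower. The Evi1-linked and gluconeogenesis lists hold Fbp1, which had been chosen from knowledge of this study. Their calls as higher are therefore not independent of that choice. Against mock, Fbp1 was the only gluconeogenesis gene that rose, and the median of that list in leukemia was -0.11.

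The pseudocounts, the filter at 5 RPKM, both scalings, the robust and trend-free spread and voom left each of the 3 gene counts within 1.5 times its value. The size of log2 fold changes of genes near 0 in a group follows the pseudocount. That of Npy in leukemia against mock ran from 4.02 with a pseudocount of 5 to 10.04 with voom, and that of Tdrd9 from 3.29 to 9.24. In preleukemia against mock Clec4b2 ran from 3.76 to 8.64 likewise, and Chi3l1 from 3.31 to 8.30, with pseudocounts of 5 and 0.1. Of the values for named genes under alternatives, 3692 stayed on their side of the threshold, 263 lost and 39 gained it. The sign turned in 4 of the 3692, all of genes that did not pass, and in none of the others. Of the named genes past the test, 41 of 68, 48 of 69 and 37 of 64 passed under each of the 18 alternatives run for single genes, which leave out the limit on the log2 fold change. In these counts a gene that the filter of an alternative left out was not taken as failing there. Other size factors, tests and filters meant for counts were not run, since the values are RPKM. Genes under the floor of 3 reads, 0.139 to 0.177 RPKM at 1 kb, cannot be told from 0.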

Other observations

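No test in this part was chosen only after the result was seen, but the genes named here as examples were chosen after their values were seen.

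Gains or losses of whole chromosomes in most leukemia cells were a hypothesis with a limit of 0.3 set beforehand. The largest difference of a chromosome's median log2 fold change, leukemia against preleukemia, from that of the others was 0.0710, on chromosome 13, over 20 chromosomes, so none reached the limit.

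Lists without a camera call of their own in a comparison gave these values. Of 14 leukemia self-renewal genes 3 rose and 4 fell in preleukemia against mock (camera adjusted p = 0.228), 3 rose and 5 fell in leukemia against mock (adjusted p = 0.179), and 2 rose and 5 fell in leukemia against preleukemia (adjusted p = 0.522). In fry the self-renewal list passed as lower in leukemia against mock (adjusted p = 0.00847) and against preleukemia (adjusted p = 0.0127). Hoxa9 stood at 6.63 RPKM in mock, 2.60 in preleukemia and was listed at 0 in leukemia, Meis1 at 6.39, 4.06 and 0.504, and Sox4, a transcription factor, at 41.9, 36.1 and 101. Of 12 monocyte and macrophage genes 5, 5 and 2 rose and 2, 3 and 3 fell in the 3 comparisons in that order (adjusted p = 0.824, 0.194 and 0.441), with a median of 0.08, or 0.20 after quantile normalization, and a mean of -0.11 in the last. Lyz2, lysozyme, stood at 67.5, 1690 and 320.4 RPKM. Of 15 hypoxia genes 3, 3 and 2 rose and 3, 3 and 3 fell (adjusted p = 0.824, 0.574 and 0.185), and the median of -0.15, or -0.09 after quantile normalization, and the mean of 0.13 in leukemia against mock differed in sign. Of 21 cholesterol and lipid genes 5, 1 and 0 rose and 0, 0 and 1 fell (adjusted p = 0.705, 0.534 and 0.763). Of 12 cell cycle inhibitors 3, 2 and 0 rose and 2, 1 and 3 fell (adjusted p = 0.812, 0.977 and 0.567). In fry the inhibitors passed as lower in leukemia against preleukemia (adjusted p = 0.0482).

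In preleukemia against mock, lists called in another comparison did not pass for the tricarboxylic acid cycle (adjusted p = 0.274; 0.00687 without mock library 2), oxidative phosphorylation (0.0884; 0.00254 without mock library 2), and antioxidants (0.967). Nor did erythroid cells (0.205; 0.00463 without mock library 2), megakaryocytes (0.257), cell cycle (0.672; 0.0113 without mock library 2), p53 targets (0.719) or fatty acid oxidation (0.812). In leukemia against mock, antioxidants (0.0745; 0.0357 without mock library 2), myeloid progenitors (0.0745; 0.0119 without leukemia library 2), dendritic cells (0.0807; 0.0280 without mock library 1), megakaryocytes (0.0599; 0.00986 without leukemia library 2), and TGF-beta signalling (0.170; 0.0154 without mock library 1) did not pass. Nor did immediate-early genes (0.132), fatty acid oxidation (0.0694; 0.00649 without mock library 2) or ribosomal proteins (0.0838; 0.0139 without leukemia library 1). In leukemia against preleukemia, nucleotide synthesis (0.538), mitochondrially encoded genes (0.538; 0.0206 without preleukemia library 1), dendritic cells (0.137; 0.0197 without preleukemia library 2 and 0.0480 without leukemia library 1), and mast cells (0.172; 0.00115 without leukemia library 2) did not pass. Nor did B-lymphoid cells (0.159), TGF-beta signalling (0.159), amino acid synthesis (0.626) or ribosomal proteins (0.522). The tricarboxylic acid cycle (0.0817) did not pass there but did without mock library 1 (0.0218), mock library 2 (0.0220), preleukemia library 2 (0.0348) or leukemia library 1 (0.0307). Likewise, immediate-early genes (0.1002) did without mock library 2 (0.0491), preleukemia library 2 (0.00308) or leukemia library 1 (0.0290).

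3 lists had 2 tested members each, too few for camera. Of T and NK cell genes Thy1 stood at 1.17, 12.4 and 2.17 RPKM in mock, preleukemia and leukemia and rose by 2.63 in preleukemia (limma adjusted p = 0.000406), and Lck by 0.80 (adjusted p = 0.0290). Of stroma and endothelium genes Pdgfrb fell in both Evi1 groups, and Pecam1 was at 27.3, 25.9 and 47.0 RPKM. Of the sex-linked genes Xist lay between 101 and 315 RPKM in all 6 libraries and the genes of the Y chromosome at or below 0.389 RPKM. The 2 tested members, Xist and Tsix, rose in leukemia against mock (median 0.89), and 1 of them rose against preleukemia. Tsix is antisense to Xist, and antisense transcripts are not separable here, so the 2 do not count as separate evidence.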
